A study of Carassius gibelio with 26 samples.

How the data were processed

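Testes of 26 two-year-old gibel carp (Carassius gibelio) males were profiled by RNA sequencing, 1 library per male. Per the labels' protocols, total RNA with an integrity number above 7 was enriched for poly(A) transcripts, made into strand-specific libraries with adapters holding molecular identifiers, and sequenced as 150 bp read pairs. The submitters' processing notes name FastQC, cutadapt 4.3, STAR 2.7.3a, Picard 2.25.6, MultiQC 1.10.1, featureCounts and Subread 2.0, with no order or role. Per the file headers, the deposited values are raw read counts made with featureCounts 2.0.6, summed over the exons of each gene in reverse-stranded mode (setting 2), from properly paired fragments of 1 to 25000 bp, with no minimum mapping quality (0). Per the file headers, the annotation was release ASM336829v1-104 of the goldfish (Carassius auratus), so reads of gibel carp were counted on the genes of a related species. The counting command held no option for multi-mapping reads, and reads of near-identical gene copies may be missing or divided; whether molecular identifiers were used to remove duplicates is not given in the sources used here. Per the file headers the table also holds the exon length of each gene, used here only to describe genes and to match them on length.

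The table held 62131 genes on 3543 sequences, among them 50 numbered chromosomes, and 0 rows naming no gene. The gene table at hand, of the gibel carp assembly carGib1.2-hapl.c with 98729 genes, matched 0 of the 62131 IDs, and the files do not pair IDs with names. The 20 gene lists fixed before the data were examined (testis and ovary genes, oocyte, germ cell, meiosis, spermatid, hormone, temperature, epigenetic and cell type markers, among others) therefore had 0 matched members and could not be tested, and sums over gene copies with the same description could not be made. Gene groups were instead read from the table: chromosomes, the mitochondrial genome, 1 Mb regions and the number of exons. These groups were chosen after the data were seen.

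Groups were taken from the sample labels: 10 diploid males (2n), 5 triploid males of group 1, 5 of group 2 and 6 of group 3. The main test was the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on the deposited counts, with TMM normalization, the edgeR filter on low counts (minimum count 10), robust estimation and Benjamini-Hochberg adjusted p under 0.05. All 16 triploid males were compared with the 10 diploid males in a 2-group model (39578 genes), and the other 6 comparisons came from 1 model with 4 groups (42352 genes). Standard errors of log2 fold changes were taken from the test's F statistic. The rule for named genes, written before the data were examined, asked for genes with an annotated name; as none had one, the 2 highest and 2 lowest log2 fold changes among changed genes with a mean log2 CPM of at least 1 in the triploid to diploid comparison are named by ID. The parts of the rule on list members and on named sex and germ cell genes had no members.

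Groups of genes were tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the groups of each comparison, and again with an estimated correlation. To see single males, the log2 CPM of each gene was set against the median of the other males of the same group (for groups 2 and 3, of both groups together), for genes with a reference log2 CPM over 3, and the median over all genes of the library was taken out. Chromosome medians carry 95% bootstrap intervals from 2000 resamples of 1 Mb windows. Measures with 1 value per library were compared with exact two-sided permutation tests, adjusted over 24 tests.

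Totals ran from 15375923 to 29503544 counts per library. A count of 0 was given a floor of 3 counts, over the group, and such bounds cover counting error only. No pair of libraries of a group held identical values; the lowest chi-square per gene within a group was 4.23, far above sampling noise. Replicate numbers in the labels did not pair samples: of 31 same-numbered pairs, 4 had a correlation of deviations over 0.1. The second number of the library names (14, 106 or 108 in diploid males, 4, 5 or 6 in group 1, 11 in group 2, 11 or 12 in group 3) has no stated meaning and was used to divide samples in alternative fits. Alternatives planned before the data were examined were other normalizations, filters and thresholds, DESeq2 1.42.0, limma-voom with sample weights, the older edgeR dispersion estimate, a replicate block, 1 surrogate variable (sva 3.50.0), other sets of samples and leaving out each male.

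The gene test was tested on simulated data with 200 changed genes. For all triploid against diploid males, on 39578 genes, it called 34.3% of genes changed 1.5-fold, 67.2% at 2-fold and 89.4% at 4-fold. For group 2 against group 3, on 42352 genes, these shares were 10.4%, 49.3% and 87.9%. A simulated chromosome raised by 0.42 in 1 male was returned as 0.39, and a chromosome lowered to -0.58 as -0.61.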

Results

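Gibel carp is a fish that reproduces sexually as diploids and, as triploid females, by gynogenesis, in which sperm activates the egg without contributing genes. Testis RNA was measured in 26 males 2 years old. The diploid males (2n, n = 10) came from sexual crosses kept at 22 °C. Triploid males were sex-reversed offspring of gynogenetic females. By the series description, group 1 (n = 5) was kept at 28 to 31 °C and came from a female whose offspring reversed sex only when warm. Group 2 (n = 5) was kept at 28 to 31 °C, and group 3 (n = 6) at 22 °C, and both came from a female whose offspring also reversed sex at 22 °C. The library names hold a second number (4, 5 or 6 in group 1, 11 in group 2, 11 or 12 in group 3) whose meaning is not given, so the number of females per group is uncertain. Offspring of 1 gynogenetic female inherit her genome, and where males of a group share a female the p-values measure the spread between related males. In the 4-group model that spread is pooled over the 4 groups, whose males were not equally alike. Ploidy, parentage and mode of reproduction differ together between 2n and 3n males. Rearing temperature differs as well for groups 1 and 2, and only group 3 shared the 22 °C of 2n. By the description, mother and group differ together between group 1 and the other triploid groups.

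Total counts per library averaged 22341355 ± 3688902 (SD, n = 10) in 2n, 24323337 ± 1353055 (n = 5) in group 1, 22694845 ± 4293486 (n = 5) in group 2 and 23957391 ± 2018247 (n = 6) in group 3. The 50% of counts in the most abundant genes came from 2682 genes ± 278 (SD) in 2n males, 2898 ± 513 in group 1, 2069 ± 57.2 in group 2 and 2097 ± 184 in group 3. Group 2 and group 3 were below 2n (exact two-sided permutation adjusted p = 0.004 for each), and group 1 did not pass the test (exact permutation adjusted p = 0.4). Genes with at least 1 count numbered 50933 ± 1080 (SD) in 2n, 52436 ± 624 in group 1, 49771 ± 782 in group 2 and 49633 ± 199 in group 3. Against 2n, group 1 was higher (exact permutation adjusted p = 0.027), group 3 was lower (adjusted p = 0.024) and group 2 did not pass (adjusted p = 0.079). The number of genes seen can depend on depth, and it was not adjusted for depth. Group 1 averaged more counts than 2n, and so did group 3, which had fewer genes. Mitochondrial genes took 0.978% ± 0.178 of counts in 2n (n = 10), 1 ± 0.114 in group 1, 0.757 ± 0.0802 in group 2 and 0.831 ± 0.051 in group 3. Group 2 lay below 2n (exact permutation adjusted p = 0.03), whereas group 3 (adjusted p = 0.085, exact permutation) and group 1 (adjusted p = 0.8) did not pass the test.

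Groups 2 and 3, reared at different temperatures, lay together. The first component of log2 CPM held 36.8% of the variance and the second 16.6%. Median rank correlations between libraries were 0.988 within group 2, 0.99 within group 3 and 0.987 between them. They were 0.953 within group 1 and 0.94 within 2n. Group 1 replicates 1 and 2 stood apart from replicates 3 to 5, with TMM factors of 1.516 and 1.447 against 1.038 to 1.067. Diploid males sharing the second number of the library name were more alike (median 0.961, 16 pairs) than those with different numbers (0.936, 29 pairs).

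**Figure D1:**
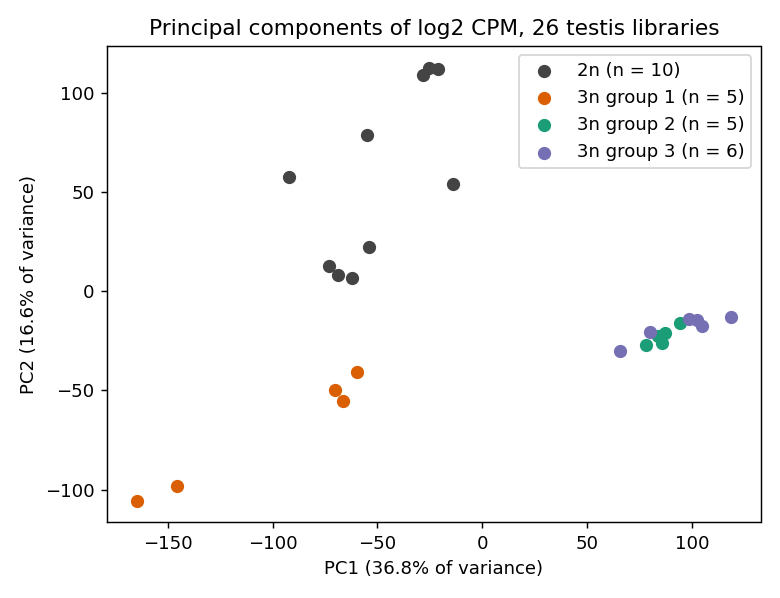
The first 2 principal components of log2 CPM, with 1 point per library and colours for the 4 groups. Groups 2 and 3 overlap at positive values of the first component, and group 1 replicates 1 and 2 lie at its low end (-164.7 and -145.6).

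By the series design, the comparison of triploid with diploid males was meant to address genes tied to reproduction. The gene ENSCARG00000050413 (unplaced scaffold QPKE01007574.1, 563230 to 576362, plus strand, annotation ASM336829v1) had 0 counts in all 10 diploid males and was present in each of the 16 triploid males. Its level was 6.54 CPM ± 0.321 (SD, n = 5) in group 1, 6.36 ± 0.853 (n = 5) in group 2 and 6.48 ± 0.946 (n = 6) in group 3. Against a floor of 3 counts over the diploid group (0.0126 CPM), it was at least 511-fold higher in triploid males (adjusted p = 9e-16, edgeR quasi-likelihood test). No other gene had 0 counts in every diploid male and at least 1 CPM in every triploid male, and 0 genes had the opposite pattern. As ploidy, parentage and mode of reproduction differ together, this does not tie the gene to reproduction. Reads were counted on goldfish genes and DNA was not measured. For this and the other named genes, a sequence missing from some males, or different in them, was therefore not checked.

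The second named gene that rose, ENSCARG00000023753 (chromosome 8, 28393114 to 28395633, minus strand, 1 exon), divided the triploid males. It stood at 11.7 CPM ± 2.39 (SD, n = 5) in group 2 and 8.99 ± 2.55 (n = 6) in group 3, against 0.0209 ± 0.0324 in group 1 and 0.0151 ± 0.0198 in 2n. Its log2 fold change over all triploid males was 8.29 ± 1.26 (SE, edgeR adjusted p = 1.9e-05), and for group 1 against group 2 it was -8.85 (adjusted p = 2e-18).

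The 2 genes with the lowest fold changes differed within the diploid males. ENSCARG00000064431 (scaffold QPKE01001629.1, 49098 to 53491) fell by 6.66 ± 0.87 (SE) on the log2 scale (edgeR adjusted p = 3.5e-06). Its mean was 96.7 CPM (58.1 to 160) in the 5 diploid males of library-name number 14, and 0.322 CPM (0.251 to 0.399) in the 4 of number 108. Triploid groups had means of 0.587 in group 1, 0.381 in group 2 and 0.436 in group 3. ENSCARG00000057221 (scaffold QPKE01006610.1, 26633 to 28375, 1 exon) fell by 5.26 ± 0.72 (edgeR adjusted p = 6.2e-06), with 27.9 CPM in number 14 and 0.562 in number 108. With diploid males limited to number 108, the log2 fold changes were 0.55 (adjusted p = 0.16) and -0.71 (adjusted p = 0.33), so both calls rested on the males of number 14.

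**Figure D2:**
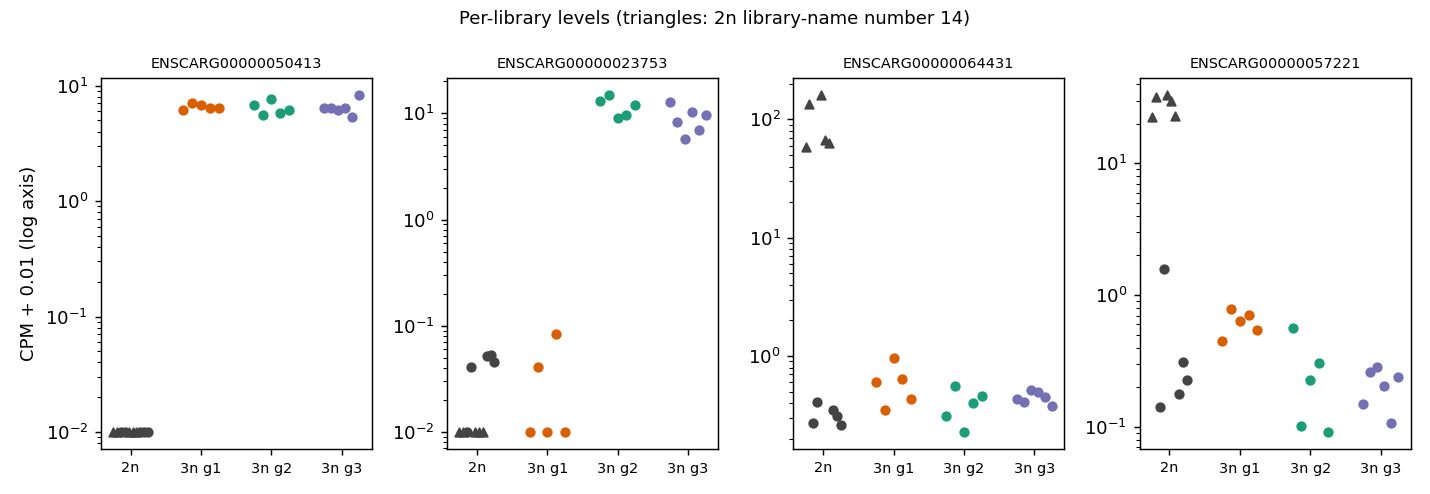
CPM plus 0.01 of the 4 named genes on a log axis, with 1 point per library and groups on the x axis. The 2n libraries of library-name number 14 are triangles, and only they are high for the 2 genes on the right (58.1 to 160 CPM and 22.4 to 32.9 CPM).

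In all, 10089 of 39578 genes differed between triploid and diploid males (edgeR adjusted p under 0.05), 4274 higher and 5815 lower in triploid males. This fit took the 16 triploid males as 1 group, though group 1 differed from group 2 in 20305 genes and from group 3 in 23921. A called gene therefore need not differ in every triploid group. With each group set against 2n, 1000 genes were higher and 2051 lower in all 3. The median absolute log2 fold change of changed genes was 0.72, and 3141 genes changed by at least 2-fold. Of the 15 mitochondrial features tested, 2 were lower in triploid males. They lie at positions 991 to 1944 (-0.94 ± 0.27 SE, edgeR adjusted p = 0.013) and 2017 to 3697 (-0.71 ± 0.2, adjusted p = 0.0094). The features have no names here, and the libraries were enriched for poly(A) transcripts. For mitochondrial features, here and below, a difference in capture and a difference in expression cannot be told apart. A region of chromosome 23 from 9000001 to 10000000 was lower, with 11 of 24 genes lower and 0 higher (median -0.59, camera adjusted p = 0.034), but the adjusted p was 1 with an estimated correlation. The count was 15539 without group 1 replicates 1 and 2, a choice made after the data were seen, and 18795 with limma-voom.

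The 3 triploid groups were each set against 2n males to address sex determination. Group 1 differed from 2n in 14395 of 42352 genes, 6691 higher and 7704 lower. A region of chromosome 16, from 2000001 to 3000000, had 16 of 33 genes higher and 4 lower (median 0.65, camera adjusted p = 0.034, and 1 with an estimated correlation). The mitochondrial feature at 2017 to 3697 was lower (-1.07 ± 0.28 SE, edgeR adjusted p = 0.0053). The count fell to 8133 without group 1 replicates 1 and 2 and to 8165 when only these 2 groups were fitted. The 4-group model pools the spread with groups 2 and 3, whose males were more alike. How much of the fall came from this was not tested. With upper quartile normalization 68.6% of changed genes were higher, against 46.5% with TMM, and the median log2 fold change of all genes moved from -0.05 to 0.12.

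Group 2 differed from 2n in 14912 genes, 5987 higher and 8925 lower, and group 3 in 18803, 7505 higher and 11298 lower. The median log2 fold change of all tested genes was -0.11 in group 2 and -0.1 in group 3. Sequence LG48F from 3000001 to 4000000 was higher in both, with 9 of 21 genes higher and 1 lower in group 2 (median 0.18, camera adjusted p = 0.042) and 10 higher and 1 lower in group 3 (median 0.3, camera adjusted p = 0.029). Chromosome 27 from 20000001 to 21000000 was lower in group 2, with 24 of 50 genes lower and 2 higher (median -0.35, camera adjusted p = 0.042). None of these regions was called with an estimated correlation (adjusted p = 1). The mitochondrial feature at 991 to 1944 was lower in group 2 (-1.21 ± 0.38 SE, edgeR adjusted p = 0.015) and in group 3 (-1.3 ± 0.35, edgeR adjusted p = 0.0047), and that at 10994 to 11290 was lower in group 2 (-0.55 ± 0.18, edgeR adjusted p = 0.02; in group 3 -0.15 ± 0.17, adjusted p = 0.46).

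**Figure D3:**
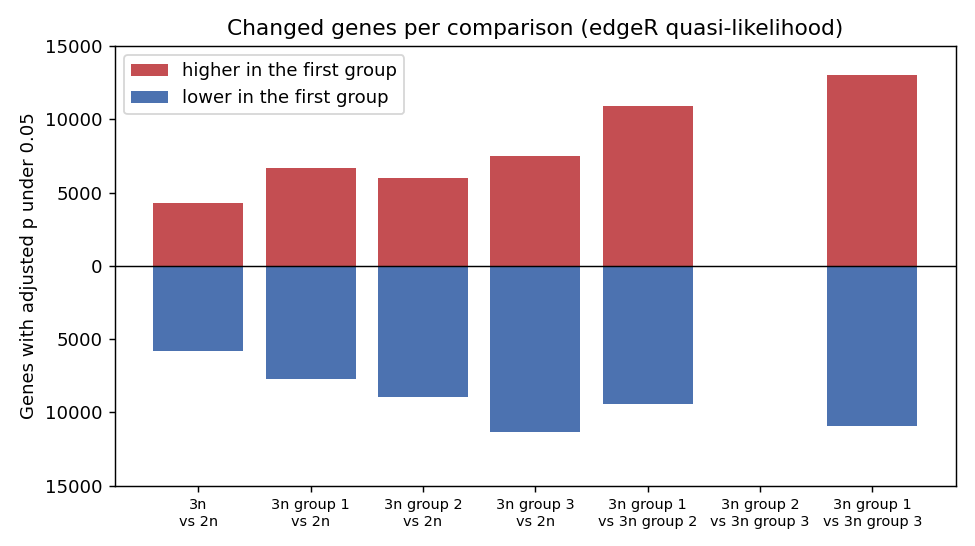
Number of changed genes (edgeR adjusted p under 0.05) in each comparison, higher above and lower below the zero line. Group 2 against group 3 has 0, and group 1 against group 3 has the tallest bars (12999 and 10922).

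Across the 3 groups, 1000 genes were higher in each and 2051 lower in each, of 28089 changed in any. Group 1 and group 2 shared 1187 higher and 2355 lower genes, where independent lists would share 946 and 1623, and 1449 genes changed in opposite directions. Group 2 and group 3 shared 5399 higher and 7786 lower genes, against 1061 and 2381 for independent lists, with 0 opposite. Group 1 and group 3 shared 1156 higher and 2330 lower genes, against 1186 and 2055 for independent lists, and 2725 were opposite. The number of opposite genes under independent lists was not worked out, so the opposite counts alone do not show divergence. Simulated unchanged groups shared 0, which leaves out the effects and so does not say how far changed lists overlap. The correlation of log2 fold changes was 0.27 for groups 1 and 2, 0.22 for groups 1 and 3 and 0.95 for groups 2 and 3. Simulated unchanged groups with the same 2n males gave 0.33, 0.35 and 0.35. Their fold changes hold noise only, so the observed correlations cannot be ranked against them. The covariance was above the simulated value for each pair, at 0.203, 0.176 and 0.854 in the same order (simulated 0.0283, 0.0281 and 0.0284). The simulation used 1 spread per gene for all groups and held no division within the 2n males. It may therefore understate the covariance that comes from sharing these males. The numbers for independent lists leave out the shared 2n males as well. With the 2n males divided into sets of 5, the correlation was 0.21, 0.17 and 0.84. Groups 1 and 2 then shared 787 higher and 1417 lower genes, groups 1 and 3 shared 777 and 1457, and groups 2 and 3 shared 3413 and 5061, as means of 10 divisions. For these divisions too, no number under independent lists was worked out.

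Group 1 and group 2 were both reared warm and came from females that differ in the temperature range of sex reversal. Their temperatures were not matched: the library names give 31 °C for group 1 replicates 1 to 3 and all of group 2, and 28 °C for group 1 replicates 4 and 5. They differed in 20305 genes, 10910 higher and 9395 lower in group 1. In group 1, 3 mitochondrial features were higher than in group 2: 10994 to 11290 (0.6 ± 0.2 SE, edgeR adjusted p = 0.017), 11284 to 12664 (0.45 ± 0.18, adjusted p = 0.048) and 12880 to 14703 (0.51 ± 0.19, adjusted p = 0.032). Mitochondrial genes together took 1% of counts in group 1 and 0.757% in group 2 (exact permutation adjusted p = 0.027). No chromosome or 1 Mb region stood out by camera, of 60 chromosome-level groups and 1208 regions. The count fell to 11865 without group 1 replicates 1 and 2. Upper quartile normalization gave 68.6% higher, against 53.7% with TMM, and moved the median of all genes from 0.1 to 0.3.

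Group 1 and group 3 differed in mother and in temperature. They differed in 23921 genes, 12999 higher and 10922 lower in group 1. Of 15 mitochondrial features, with log2 fold changes from -0.66 to 0.86, 1 was called, that at 14700 to 15221, lower in group 1 (-0.66 ± 0.27 SE, edgeR adjusted p = 0.037). The mitochondrial share of counts was higher in group 1, 1% against 0.831% (exact permutation adjusted p = 0.024). No chromosome and 0 of 1208 regions passed camera. Among 1-exon genes, 586 of 1684 were higher and 264 lower, with a median of 0.33, and this set did not pass camera (p = 0.056, and p = 0.089 with an estimated correlation). Upper quartile normalization gave 69.6% higher, against 54.3% with TMM, and a median of 0.33 against 0.09.

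Group 2 and group 3, from the same kind of female but reared warm and at 22 °C, differed in 0 of 42352 genes (edgeR). At an unadjusted p under 0.05 there were 1074 genes, or 2.54% of those tested. With no differences a calibrated test gives a share of 0.05, so the test may have been conservative for this pair. Its spread was pooled with group 1 and 2n, whose males were less alike. Median rank correlations were 0.953 in group 1 and 0.94 in 2n, against 0.988 in group 2 and 0.99 in group 3. The 0 called genes therefore do not show that temperature had no effect. DESeq2 called 1 gene, limma-voom 1, and edgeR on these groups alone 2. Of the sets tested by chromosome, 4 passed camera with a preset correlation, with 0 genes called in any of them: chromosome 22 (781 genes, median log2 fold change 0.15, camera adjusted p = 2.4e-07), chromosome 47 (392 genes, median 0.05, adjusted p = 0.0077), chromosome 29 (572 genes, median -0.11, adjusted p = 6.2e-08) and the mitochondrial sequence (15 features, median -0.2, adjusted p = 1e-04). With an estimated correlation none passed (adjusted p = 0.67 for chromosome 22 and 0.97 for the other 3). Of 1208 regions of 1 Mb, 18 passed camera with the preset correlation, 12 higher on chromosome 22 and 6 lower on chromosome 29, and 0 with an estimated correlation (adjusted p = 0.98 for each of the 18). The mitochondrial share of counts, 0.757% in group 2 and 0.831% in group 3, did not pass its test either (exact permutation adjusted p = 0.13). Single males set 2 of these values: without group 2 replicate 3 the chromosome 29 median was -0.01 (adjusted p = 0.98), and without group 3 replicate 2 the chromosome 47 median was -0.02 (adjusted p = 0.96). The chromosome 22 median was 0.08 without group 2 replicate 2 and 0.11 without replicate 5.

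Per male, 4 of 1300 pairs of a male and a chromosome deviated by over 0.25 in median log2 from the other males, all in groups 2 and 3. Chromosome 22 was raised in group 2 replicate 2 (median 0.36, 95% interval 0.32 to 0.41, 270 genes) and in group 2 replicate 5 (0.35, 0.33 to 0.37, 268 genes). Chromosome 29 was lowered in group 2 replicate 3 (-0.63, interval -0.69 to -0.56, 248 genes). Chromosome 47 was lowered in group 3 replicate 2 (-0.54, interval -0.58 to -0.5, 203 genes). From 88.9% to 99.5% of the genes on these chromosomes deviated in the direction of the median. Simulated shifts were placed only in males of groups 2 and 3, so detection in 2n and group 1 was not checked. The median of a whole chromosome can also miss a part of it. In 2n replicate 7 the first 6 Mb of chromosome 47 had a median of 0.52 (98 genes).

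**Figure D4:**
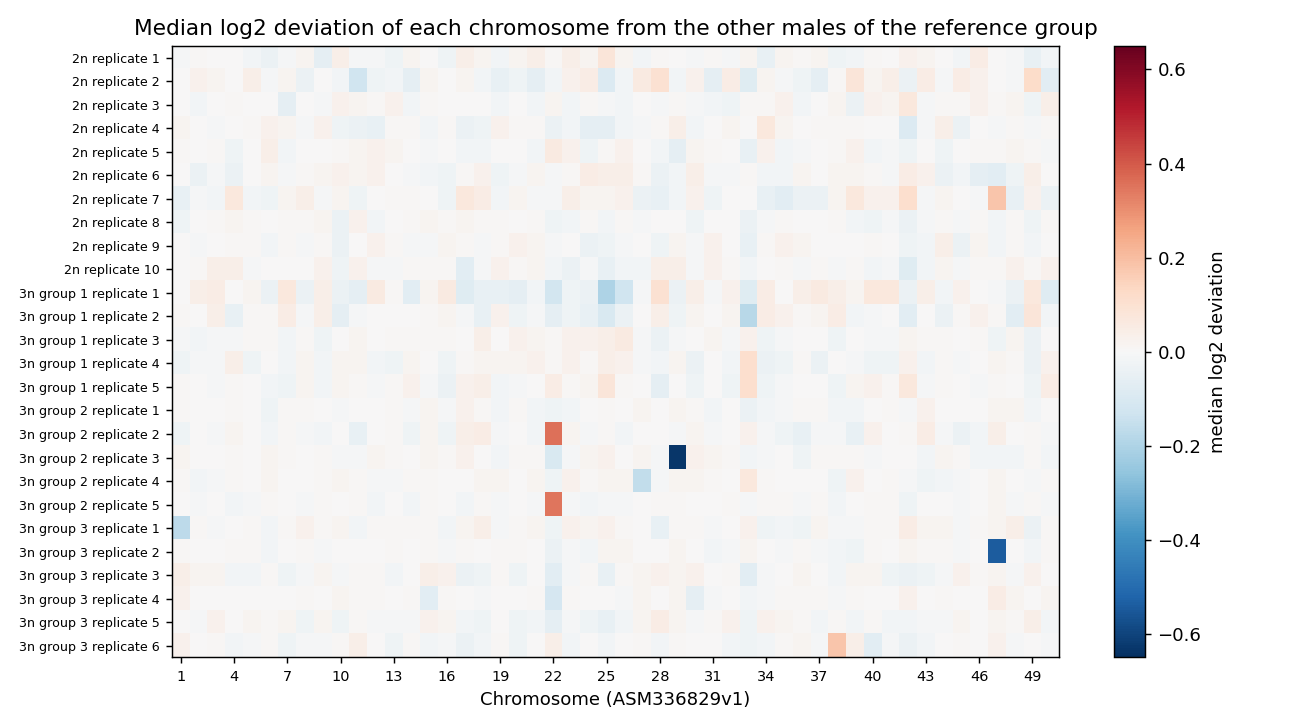
Median log2 deviation of each numbered chromosome (x axis) in each male (y axis) from the other males of its reference group, red higher and blue lower. The 4 strongest cells are chromosome 22 in group 2 replicates 2 and 5, chromosome 29 in group 2 replicate 3 and chromosome 47 in group 3 replicate 2.

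**Figure D5:**
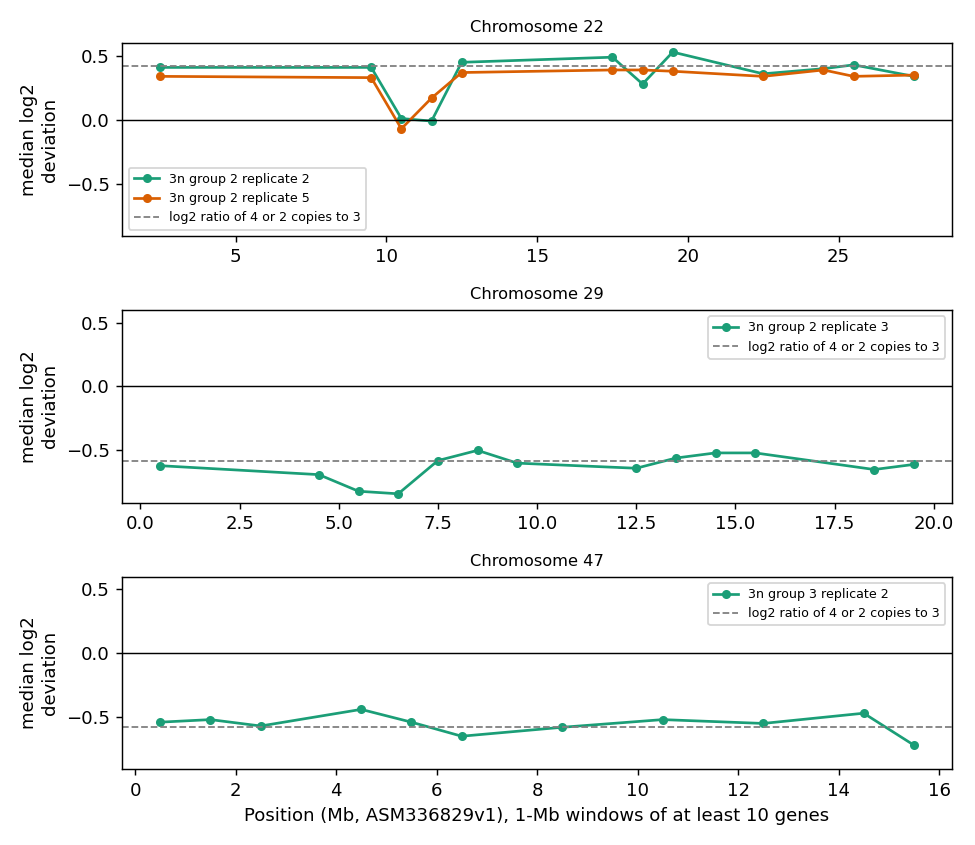
Median log2 deviation in 1 Mb windows of at least 10 genes along chromosomes 22, 29 and 47 in the 4 males, with dashed lines at the log2 ratio of 4 or 2 copies to 3 (0.42 and -0.58). On chromosome 22, of the windows shown, those from 10 to 12 Mb have the lowest values in both males (0.01 and -0.01 in replicate 2, -0.07 and 0.17 in replicate 5).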

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

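The tests on single males and on group 1 replicates were chosen after the results were seen, except the matching on level and length; the counts over other splits of the samples were planned. Of 35 sets of per-library values checked for a library far from its group, 3 held one, and chance gives about 1 in 20. A further 12 sets, on chromosomes 22, 29 and 47, were taken because single males had been seen to shift there, so the 3 they held cannot be set against that rate.

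Chromosome 29 in group 2 replicate 3 (-0.63) and chromosome 47 in group 3 replicate 2 (-0.54) lay far from the other males, and chromosome 22 was raised in group 2 replicates 2 and 5. With chromosomes 22, 29 and 47 set aside, the largest absolute median of a chromosome in these males was 0.05. Chromosome 22, left out there, was at -0.1 in group 2 replicate 3. The median over each library had been taken out first, so a shift of a whole library by normalization or depth could not show. These values say only that shifts of this size were not spread over the other chromosomes. Genes elsewhere matched on expression level and length had a largest absolute median of 0.01, which argues against a bias of that kind. A candidate explanation is 1 copy of 3 gained or lost, and this stays open: 1 of the 4 intervals, that of chromosome 29, held the log2 ratio of such a change (0.42 or -0.58) before rounding, and expression need not follow copy number in proportion. Among windows of at least 10 genes, 10 of 12 on chromosome 22 in each male lay nearer the ratio of such a change than 0. So did 13 of 13 on chromosome 29 and 11 of 11 on chromosome 47. A shift of similar size from another cause would give this too. On chromosome 22, the windows from 10 to 12 Mb were lowest in both males, at 0.01 and -0.01 in replicate 2 and -0.07 and 0.17 in replicate 5. Outside that region the gene medians were 0.4 in replicate 2 and 0.36 in replicate 5. DNA was not measured, so chromosome-wide regulation and mosaic tissue stay open, and no biological explanation from the design was tested.

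Group 1 replicates 1 and 2 stood apart from replicates 3 to 5. Depth does not account for this, as replicate 1 had 23515626 counts, inside the range of replicates 3 to 5. Replicate 3, named for the same temperature of 31 °C, lay 75.6 units of the first component from the nearer of them and at most 10.4 from replicates 4 and 5. Replicate 5, which shares its library-name number with replicate 1, lay 105.1 units from it. A difference in the cell makeup or stage of the testis stays open and untested, as the genes have no names.

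In 2n replicate 7 the chromosome 47 median was 0.18, set by the first 6 Mb (98 genes, median 0.52, against -0.11 in the rest). The 50% of counts came from 3334 genes in 2n replicate 2 (others 2345 to 2848) and from 2170 in group 2 replicate 5 (others 2034 to 2055). ENSCARG00000050413 stood at 8.23 CPM in group 3 replicate 6 (others 5.36 to 6.39).

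The effects against 2n differed between groups 1 and 2 in 20305 genes and between groups 1 and 3 in 23921 genes. As 2n cancels out, these are the direct edgeR contrasts between the groups given above and not a further result.

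For 6 of the 7 comparisons, 1 of 100 splits, the real one, gave as many genes. This argues against a chance division of unrelated males. The splits exchanged single males, though males of a group may share a mother or cross. They therefore cannot exclude chance differences between a few families. For all triploid against diploid males the real split gave 10089 and the highest other 152. The highest others were 5636 for group 1 against 2n (real 14395), 6997 for group 2 against 2n (14912), 7771 for group 3 against 2n (18803), 118 for group 1 against group 2 (20305) and 13762 for group 1 against group 3 (23921). The 13762 came from exchanging 1 male of each group, and the 7771 from setting 6 diploid males against the other 4 together with all of group 3. For group 2 against group 3 the real count was 0, which every split reaches (100 of 100, highest other 13), so the number of splits says nothing on chance there.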

How the results depend on the processing

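The settings without group 1 replicates 1 and 2, and the chromosome sets, were chosen after the data were seen. Leaving out 1 male at a time gave 9018 to 12763 genes for all triploid against diploid males, 11116 to 15662 for group 1 against 2n, 12042 to 15779 for group 2 against 2n, 15718 to 19700 for group 3 against 2n, 16805 to 20987 for group 1 against group 2, 21077 to 24157 for group 1 against group 3 and 0 to 0 for group 2 against group 3. Upper quartile and DESeq2 size factors, both filters, the older edgeR estimate, the surrogate variable and diploid males of either library-name number stayed within 1.5 times of each count. Changes of at least 2-fold numbered 3141, 4983, 6140, 7246, 9290 and 11305 in the same order, and an adjusted p under 0.01 gave 5699, 8247, 8397, 11878 and 13104 for the first 5. For all triploid males the counts were 18795 with limma-voom, 15450 with the 3 triploid groups weighted equally and 15539 without group 1 replicates 1 and 2. Without these 2 males group 1 gave 8133 genes against 2n and 11865 against group 2, and with only the groups compared 8165 against 2n. Group 2 against group 3 had 1 gene with limma-voom, 1 with DESeq2 and 2 with only these groups; the cause was not tested.

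The labels' replicate numbers do not pair the samples (median correlation of deviations -0.001 over 31 pairs), and a replicate block gave 6537 genes for all triploid males and stayed within 1.5 times elsewhere. ENSCARG00000064431 turned to 0.55 with diploid males of number 108. The chromosome 47 median turned to 0.00 with males of number 11 only and to -0.02 without group 3 replicate 2, the male whose chromosome 47 was low, and ran up to 0.07 without other males. The gene list tests and the sums over gene copies were not run, as no ID had a name. In simulated group 2 against group 3 data on 42352 genes, 10.4% of 1.5-fold changes were called, and depth was not varied.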

Other observations

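The comparison of diploid males by library-name number, and the lists of smaller shifts, were chosen after the data were seen. Diploid males of number 14 (n = 5) and 108 (n = 4) differed in 5663 of 39725 genes by edgeR, 2878 higher and 2785 lower in number 14. Of 100 splits of these 9 males, 1 gave as many, the real one, and the highest other gave 3501. This does not decide on chance, as males of the same number had already been seen to be alike. The number's meaning is not given, so family, batch and other differences cannot be separated.

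Smaller whole-chromosome deviations, between 0.15 and 0.25, were seen for chromosome 27 in 3n group 2 replicate 4 (-0.16, 18% of 451 genes above 0), chromosome 1 in 3n group 3 replicate 1 (-0.17, 20.6% of 344 genes above 0) and chromosome 38 in 3n group 3 replicate 6 (0.18, 83.2% of 340 genes above 0). In group 1, chromosome 25 of replicate 1 (-0.2, 299 genes) and chromosome 33 of replicate 2 (-0.18, 44 genes) deviated, with 39.1% and 36.4% of genes above 0.

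Genes at 0 counts in every male of 1 side and at least 1 CPM in every male of the other were few: 3 present in group 1 and absent from group 2, 1 the other way, and 0 between groups 2 and 3 in either direction. Between the diploid males of numbers 14 and 108 there were 2 such genes, both present in number 14.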
